A study of Mus musculus with 35 samples.

How the data were processed

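Polyadenylated RNA of sorted CD8 T cells was sequenced from its 3′ end in bulk, per the labels' protocols, after cells were sorted into lysis buffer. Complementary DNA was primed with oligo-dT carrying sample barcodes and unique molecular identifiers (UMIs), pooled, amplified and tagmented, and was read on a NextSeq 500 with 75 cycles for the cDNA and 16 cycles for barcodes and UMIs. The deposited values are whole-number counts per gene symbol, not normalized, for 22865 genes, with 1 table for the whole series. Per the submitters' processing notes, the genome build was GRCm38.p6 and DESeq2 1.14.1 was used by the authors. The aligner, the counting program, the annotation, the use of strand and whether counts are reads or collapsed UMIs are not given in the sources used here. A 3′ tag measures the end of a transcript, so that the counts carry no length bias to correct. Overlapping genes, antisense partners and near-identical copies such as the T cell receptor gamma constant genes, globins and Klra genes cannot be told apart with certainty. Of the symbols, 22662 of 22865 matched the names of the reference annotation, and 17 read as calendar dates and are not named. Coordinates are those of GENCODE M21 on GRCm38, 1-based, for the whole gene.

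The labels name 35 samples in 6 groups, and 34 columns of the table matched a sample by name. Another 1 column of values matched no sample and was used in no step, and the sample CD-HFD liver CXCR6pos replicate 6 was not analysed here. ND liver CXCR6neg replicate 1 and ND spleen replicate 6 were identical in all 22865 genes. Since the labels put them in different groups, both were left out and 32 libraries were fitted, a departure from the planned fit of 35, and the fits with that library kept in one or both groups are given as alternatives. Total counts ran from 15633 to 978896 with a median of 308123. Libraries under 0.2 times that median, namely ND CXCR6pos replicate 1 and CD-HFD CXCR6pos replicate 5, were kept and left out in an alternative.

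Genes were filtered with filterByExpr by group, which kept 6174 genes, and counts were normalized by TMM. Differences were tested with the quasi-likelihood test of edgeR 4.0.16 (estimateDisp, glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, with 1 coefficient per group, all 6 groups in 1 fit and no block. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. The common dispersion was 0.0149, a biological coefficient of variation of 0.122, and the median log2 fold change over all genes was between -0.02 and 0.00 in every comparison. Group levels are means of TMM-scaled CPM with SD. Where a group had no count, a bound on the fold used 3 counts over the group, and with 1 to 3 counts an exact 95% interval of the ratio of counts is given, except for interactions. Both cover counting error only.

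The comparisons were CXCR6pos against CXCR6neg in the liver under each diet, CD-HFD against ND in each of the 3 fractions, liver CXCR6neg against spleen CX3CR1neg under each diet, and both interactions with diet. Genes are named by a rule: past the threshold with a mean of at least 20 CPM in the higher group, up to 12 of the largest changes in each direction, or 6 for the interactions and the liver and spleen comparisons. Up to 4 members of each list with the smallest p-values and the genes Cxcr6, Cx3cr1, Cd8a, Cd8b1, Cd3e, Pdcd1, Tox, Foxo1, P2rx7, Tcf7, Fasl, Gzmb and Il15ra are named in addition, and with no gene past the threshold the 5 smallest p-values. Predicted or unnamed models, accession-like names and pseudogene names, and immunoglobulin and T cell receptor segments are counted but not named. The text gives part of the genes the rule allows, for the most part those whose call held without each library in turn, and says where a gene outside the rule was chosen after its value was seen. One gene is not reported here. The comparisons, the rule, the gene lists and the alternatives not stated otherwise were fixed before the data were examined.

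A total of 35 gene lists covered T cell programs (tissue residency, recirculation, naive and memory, cytotoxic, inhibitory receptors and exhaustion, FOXO1 targets, purinergic and acetate genes, chemokine receptors, IL-2 and IL-15 signalling, NF-kB and TNF, interferon, immediate-early and heat-shock, proliferation, glycolysis, oxidative phosphorylation, fatty acid and cholesterol, ER stress, TGF-beta, apoptosis). They also covered T cell identity, sex-linked genes, other cells (B cells, hepatocytes, Kupffer cells and macrophages, neutrophils, dendritic cells, NK cells, unconventional T cells, CD4 and regulatory T cells, endothelial, stellate and fibroblast, erythroid, platelets), and ribosomal protein and mitochondrially encoded genes. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. Camera compares a list with the other genes, and fry tests whether its genes move on balance in one direction. The dendritic cell list holds Cd8a and Bst2, the NK cell list holds cytotoxic genes and the CD4 and regulatory T cell list holds Ctla4, Ikzf2 and Tnfrsf4, all of which CD8 T cells or other lists share. A list of 17 plasmacytoid dendritic cell markers was written after the data were seen.

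Alternatives were DESeq2 1.42.0, RLE in place of TMM, no filter on low counts (22378 genes), only the groups compared, voom with quality weights and the log10 total count as a covariate. Further ones were the replicate number as a block in the groups compared, with and without that covariate, shallow libraries left out, and each library left out in turn. The choices added later were the library held in 2 columns kept in both groups, in the liver or in the spleen, and the ND CXCR6pos library lowest and the ND CXCR6neg library highest in Cxcr6 left out together, alone and with the shallow libraries. Each comparison was also repeated on 100 splits of its libraries, the real one included. The procedure was tested on simulated data with 200 changed genes. Of these, 47.8% of 2-fold and 92.4% of 4-fold changes were recovered for CXCR6pos against CXCR6neg under CD-HFD. The shares were 67.2% and 93.9% for the same under ND, and 85.1% and 98.5% for diet in the spleen. Each is a share of 67 genes changed 2-fold or 66 changed 4-fold among 6174, in a single simulated draw. Every library was drawn from the same mean profile with a spread per gene. A spread particular to some groups, such as that of Cxcr6 under ND, was therefore not simulated.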

Results

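CD8 T cells were sorted from the liver and spleen of C57BL/6 mice aged 13 months that were kept on the diets labelled ND and CD-HFD, and their polyadenylated RNA was sequenced in bulk from the 3′ end. Liver cells were divided by the chemokine receptor CXCR6 into CXCR6pos and CXCR6neg fractions, and spleen cells were taken from the fraction without the chemokine receptor CX3CR1 (CX3CR1neg). The comparisons used 32 libraries: 6 of ND liver CXCR6pos, 5 of CD-HFD liver CXCR6pos, 4 of ND liver CXCR6neg, 6 of CD-HFD liver CXCR6neg, 5 of ND spleen and 6 of CD-HFD spleen. Total counts ran from 15633 to 494700 (median 322144) in ND CXCR6pos, from 57168 to 369055 (median 182006) in CD-HFD CXCR6pos, from 165811 to 419019 (median 271066) in ND CXCR6neg and from 84808 to 355845 (median 249030) in CD-HFD CXCR6neg. They ran from 169106 to 688547 (median 427360) in ND spleen and from 225036 to 978896 (median 523614) in CD-HFD spleen. ND liver CXCR6neg replicate 1 and ND spleen replicate 6 held the same count for all 22865 genes, so that they differed by less than the sampling noise, and because their labels put them in different groups neither was used in a comparison. The labels do not say that replicates were separate animals, so p-values measure the spread between these samples only.

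The sort was checked first on the genes of its own gates. Cxcr6 (chromosome 9, 123806475 to 123811760, plus strand, GRCm38) was at 724 ± 130 TMM-scaled CPM (SD, n = 5) in CD-HFD CXCR6pos and 86.7 ± 29.5 (n = 6) in CD-HFD CXCR6neg, with no overlap between libraries. Under ND the fractions overlapped, at 505 ± 238 CPM (n = 6) in CXCR6pos and 228 ± 169 (n = 4) in CXCR6neg. The library labelled ND CXCR6pos replicate 6 held 201 CPM of Cxcr6, the lowest of CXCR6pos, and the library labelled ND CXCR6neg replicate 4 held 450 CPM, the highest of CXCR6neg. ND CXCR6pos replicates 1 and 2 (295 and 449.8 CPM) and ND CXCR6neg replicate 5 (227 CPM) also lay within the range of the other fraction. Cx3cr1 (chromosome 9, 119901616 to 120069879, minus strand) was at 11.8 ± 11.3 CPM (n = 5) in ND spleen and 11.7 ± 8.28 (n = 6) in CD-HFD spleen, against group means of 35.8 to 134 CPM in the liver. Cd8a (chromosome 6, 71373427 to 71379173, plus strand), Cd8b1 (chromosome 6, 71322788 to 71337494, plus strand) and Cd3e (chromosome 9, 44998740 to 45009627, minus strand) code for the CD8 coreceptor and a CD3 chain. Their group means were 880 to 1485, 1724 to 2031 and 895 to 1891 CPM.

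**Figure D1:**
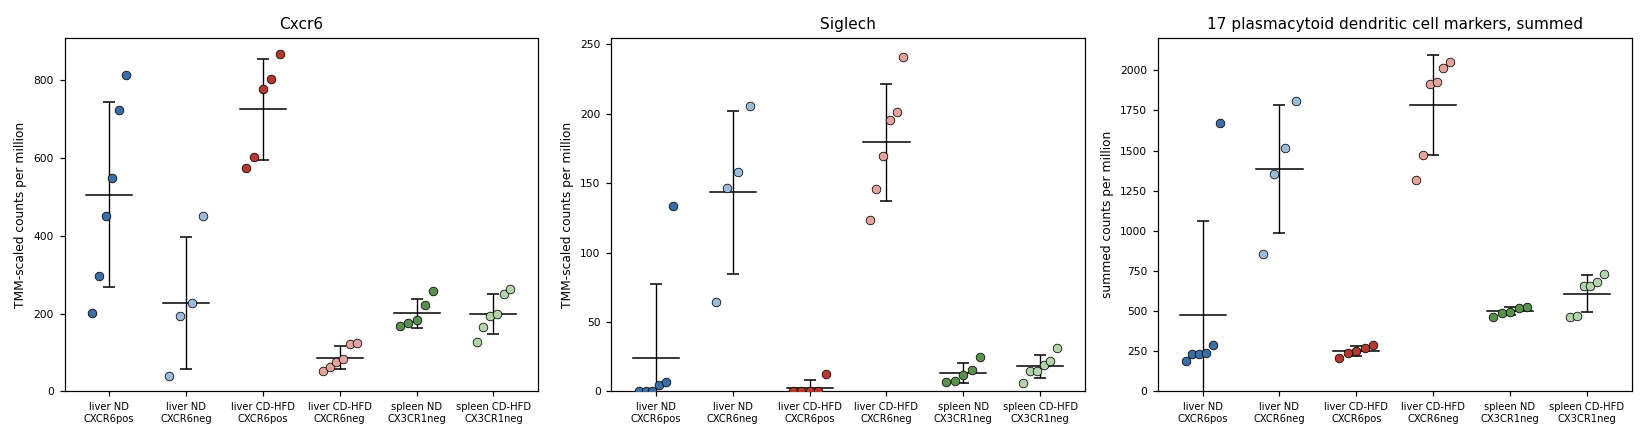
TMM-scaled CPM of Cxcr6 and Siglech, and summed CPM of 17 plasmacytoid dendritic cell markers, in each of the 32 libraries (points) by group, with the mean (line) and SD (bar). Siglech was at 133 CPM in the library labelled ND CXCR6pos replicate 6 and at most 12.4 CPM in the other CXCR6pos libraries, while the 10 CXCR6neg libraries held 64.3 CPM or more.

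The first question was what distinguishes hepatic CD8 T cells with CXCR6 from those without it under CD-HFD. CXCR6pos cells had more Pdcd1, which codes for the inhibitory receptor PD-1 (533 against 136 CPM, log2 fold change 2.00 ± 0.22, SE, adjusted p = 2.26e-08, n = 5 and 6). They had 2.22-fold more Tox, a transcription factor of exhausted T cells (1.15 ± 0.21, adjusted p = 0.000114). They had 5.13-fold less Tcf7, which codes for the T cell factor TCF1 (-2.36 ± 0.20, adjusted p = 2.4e-18). S1pr1 was 4.45-fold lower (-2.15 ± 0.19, adjusted p = 1.45e-17) and codes for the receptor for egress from tissue. Gzmb, the protease granzyme B, was 2.89-fold higher (1.53 ± 0.31, adjusted p = 0.000961) and Fasl, the ligand of the death receptor CD95, 1.59-fold higher (0.67 ± 0.14, adjusted p = 0.000158). Of 6174 genes tested, 294 were higher and 394 lower in CXCR6pos.

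Among the largest increases under CD-HFD were the adhesion receptor gene Adgrg1 (15.6-fold, 3.96 ± 0.42), Osgin1 (15.4-fold, 3.94 ± 0.59) and Chn2 (9.44-fold, 3.24 ± 0.47). The macrophage growth factor gene Csf1 (9.05-fold, 3.18 ± 0.52), the sorted marker Cxcr6 (8.22-fold, 3.04 ± 0.38) and Cd244a (8.12-fold, 3.02 ± 0.56) followed. The T cell receptor gamma constant genes Tcrg-C4 (2.78 ± 0.30) and Tcrg-C2 (2.56 ± 0.39) also rose, with the reservation that these near-identical copies share reads. Among the largest decreases were Ccr9, Spib and Smim5, which had no count in the 5 CXCR6pos libraries. They were at least 19.0-fold, 13.5-fold and 13.2-fold lower when 3 counts over the group are taken as the floor. Siglech (chromosome 7, 55768178 to 55778925, plus strand), a surface lectin of plasmacytoid dendritic cells, had 2 counts in CXCR6pos and 230 in CXCR6neg, a ratio of 91.2 (95% counting interval 25 to 758). Klk1 (ratio 75.4, interval 13.2 to 3008), Ctsh (108, interval 19.0 to 4293) and Cox6a2 (39.9, interval 13.4 to 196) fell likewise. Irf8 (-1.94 ± 0.48) and Tcf4 (-3.24 ± 0.70), transcription factors of plasmacytoid dendritic cells named here after their values were seen, fell as well. These intervals and floors cover counting error only.

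By fixed lists, 16 of 20 tested inhibitory receptor and exhaustion genes rose and none of the 20 fell under CD-HFD (18 higher adjusted over the list alone, camera adjusted p = 5.9e-15). Among them were Entpd1 (1.91 ± 0.24), Nr4a2 (1.71 ± 0.22) and Cd38 (1.66 ± 0.29). Of 19 naive and memory genes, 15 fell and 1 rose (15 lower and 2 higher adjusted over the list alone, adjusted p = 1.77e-19). Il7r, the IL-7 receptor, was at -2.55 ± 0.25. Of 19 recirculation genes, 12 fell and 1 rose (13 and 1 adjusted over the list alone, adjusted p = 9.96e-17), including Klf2 (-1.16 ± 0.12) and Ly6c2 (-1.82 ± 0.12). Of 16 FOXO1 targets, which share members such as Klf2, S1pr1, Ccr7, Il7r and Tcf7 with these lists, 8 fell and 0 rose (8 lower and 1 higher adjusted over the list alone, adjusted p = 2.53e-11). Of 19 tissue residency genes, 10 rose and 1 fell (10 and 3 adjusted over the list alone, adjusted p = 4.82e-06). Bhlhe40 was at 1.07 ± 0.13 and Rgs1 at 1.83 ± 0.22. Beside these falls, Siglech and the other plasmacytoid dendritic cell genes moved with the CXCR6neg fraction. Ccr9 and Tdrp, which had 0 and 1 counts in CXCR6pos (for Tdrp a ratio of 42.1, 95% counting interval 7.23 to 1692), are members of the naive and memory list.

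Of 23 cytotoxic genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone, adjusted p = 0.000823), including Nkg7 (0.86 ± 0.09), Ccl5 (0.93 ± 0.10), Prf1 (0.72 ± 0.15) and Gzma (1.85 ± 0.38). This call was lost at adjusted p = 0.124 with an estimated correlation. T cell identity genes gave 7 of 16 higher and 0 lower (7 and 0 adjusted over the list alone, adjusted p = 8.02e-06, adjusted p = 0.124 with an estimated correlation). Cd3g was at 0.99 ± 0.10, Cd3e at 0.81 ± 0.10 and Cd8a at 0.73 ± 0.11. Ribosomal protein genes gave 31 of 79 lower and 0 higher (35 and 0 adjusted over the list alone, adjusted p = 7.66e-10, adjusted p = 0.246 with an estimated correlation). Mitochondrially encoded genes gave 5 of 10 lower and 0 higher (5 and 0 adjusted over the list alone, adjusted p = 0.00539, adjusted p = 0.0977 with an estimated correlation). Apoptosis genes gave 5 of 20 higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 0.0301), with adjusted p = 0.146 with an estimated correlation. No call by camera was made for purinergic and acetate genes, chemokine receptors, IL-2 and IL-15 signalling, NF-kB and TNF response, interferon response, immediate-early genes, proliferation, glycolysis, oxidative phosphorylation, fatty acid and cholesterol genes, ER stress or TGF-beta response. Their adjusted p ran between 0.23 and 0.714. Within them, the STAT5 target Cish rose (1.40 ± 0.27), while Nfkbia (-0.95 ± 0.13) and Fos (-1.17 ± 0.21) fell. Fos did not pass with the library held in 2 columns kept in both groups (adjusted p = 0.106) or in the liver (0.114).

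Markers of other cells under CD-HFD moved in both directions. Of 9 B cell genes, 5 fell and 0 rose in CXCR6pos (6 and 0 adjusted over the list alone, adjusted p = 4.14e-08), among them Ly6d (-4.77 ± 0.90), Cd74 (-2.23 ± 0.56) and Ighm (-1.77 ± 0.40). Igkc, the kappa light chain, was at 0.64 ± 0.57 (adjusted p = 0.597). Of 3 dendritic cell genes, Siglech and Bst2 (-1.50 ± 0.24) fell and Cd8a, which CD8 T cells express, rose (the same 2 and 1 adjusted over the list alone, adjusted p = 0.0301, adjusted p = 0.146 with an estimated correlation). The unconventional T cell list had 2 of 4 genes higher and 0 lower, both gamma constant genes (2 and 0 adjusted over the list alone, adjusted p = 0.0188, adjusted p = 0.124 with an estimated correlation). Trdc, the delta constant gene, had 2 counts in CXCR6pos and 16 in CXCR6neg, a ratio of 6.35 (95% counting interval 1.49 to 56.9). The CD4 and regulatory T cell list had 2 of 5 genes higher and 0 lower (2 and 0 adjusted over the list alone, adjusted p = 0.0359, adjusted p = 0.195 with an estimated correlation). NK cell genes (2 higher and 3 lower of 10, with Tyrobp at -4.45 ± 0.65), Kupffer and macrophage genes (0 higher and 1 lower of 3) and erythroid genes (0 of 6 in either direction) passed no list test. Lists with fewer than 3 tested genes are given as summed CPM over group means. Hepatocyte genes were at 64.6 to 221, endothelial genes at 26.7 to 86.9 and stellate and fibroblast genes at 1.54 to 5.22. Neutrophil genes were at 0.468 to 3.28, platelet genes at 2.74 to 8.40 and sex-linked genes at 138 to 197. Of the other genes named in every comparison, Cd8b1 (0.16 ± 0.10) and Cx3cr1 (-0.54 ± 0.34) did not pass. Neither did Il15ra (chromosome 2, 11705290 to 11734317, plus strand, 0.97 ± 0.39), Foxo1 (chromosome 3, 52268336 to 52353221, plus strand, -0.55 ± 0.43) or P2rx7 (chromosome 5, 122643911 to 122691432, plus strand, -1.07 ± 0.93).

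**Figure D2:**
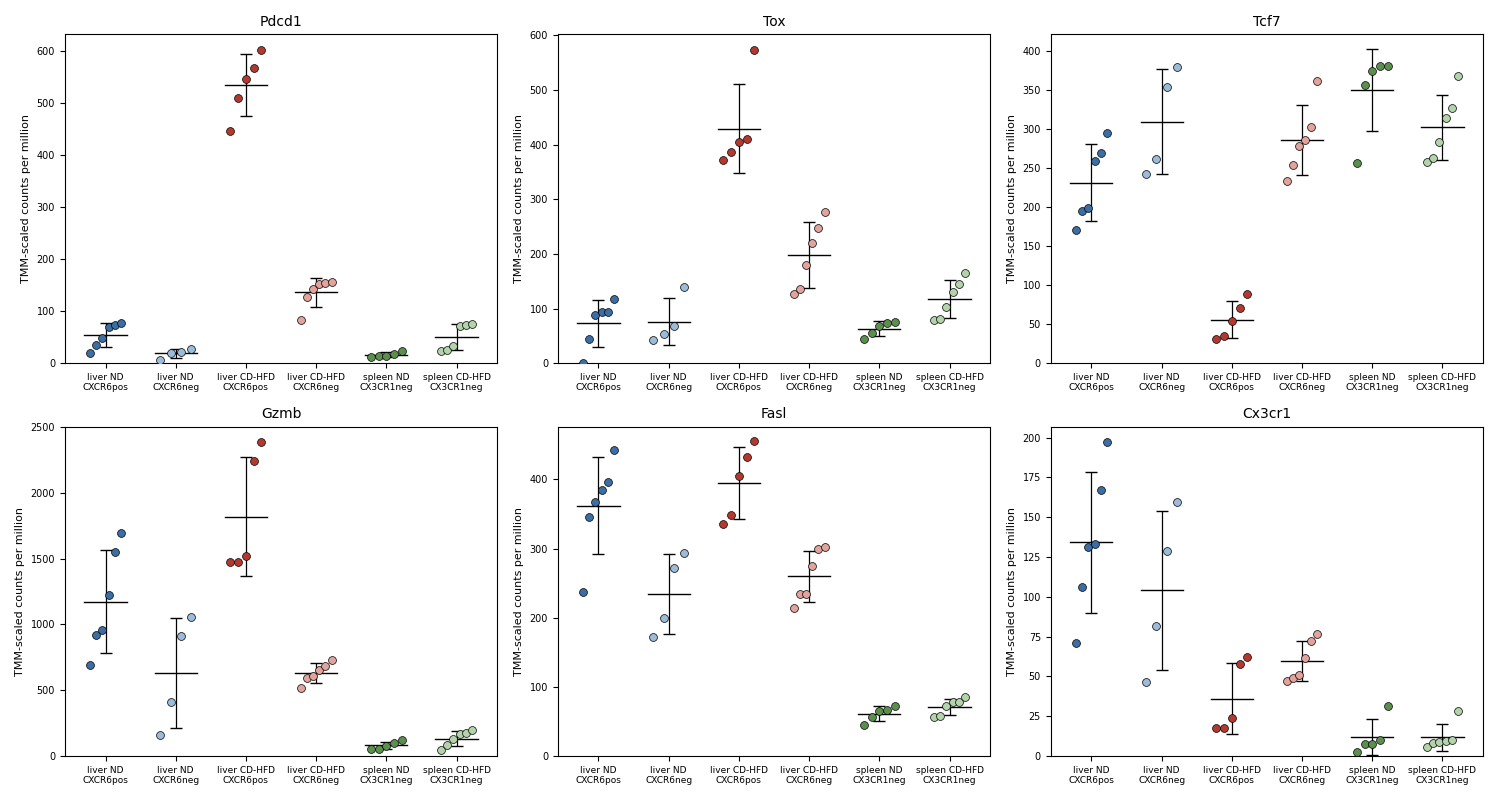
TMM-scaled CPM of Pdcd1, Tox, Tcf7, Gzmb, Fasl and Cx3cr1 in each of the 32 libraries (points) by group, with the mean (line) and SD (bar). Pdcd1 was at 533 ± 59.6 CPM (n = 5) in CD-HFD CXCR6pos and 136 ± 28.2 (n = 6) in CD-HFD CXCR6neg, against 54.1 ± 23.5 (n = 6) and 19.3 ± 9.17 (n = 4) under ND.

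The same fractions were then compared under ND, where 2 genes passed. Both were lower in CXCR6pos: Grn, the growth factor progranulin (2.52-fold, -1.33 ± 0.27, adjusted p = 0.0461, n = 6 and 4), and n-R5-8s1, a ribosomal RNA gene (-2.84 ± 0.57, adjusted p = 0.0461). Cxcr6 was at 1.07 ± 0.34 and did not pass (adjusted p = 0.307). Neither did Pdcd1 (1.25 ± 0.47), Tox (0.22 ± 0.32), Tcf7 (-0.42 ± 0.15), Gzmb (0.89 ± 0.33) or Fasl (0.51 ± 0.14). The same held for Cd8a (0.32 ± 0.11), Cd8b1 (0.03 ± 0.11), Cd3e (0.05 ± 0.10), Cx3cr1 (0.18 ± 0.23), Foxo1 (-0.24 ± 0.35), P2rx7 (0.58 ± 0.49) and Il15ra (0.00 ± 0.27). As whole lists, cytotoxic genes were higher (median log2 fold change 0.31 over 23 genes, camera adjusted p = 2.24e-08) and naive and memory genes lower (median -0.60 over 19 genes, adjusted p = 2.52e-08). Both passed at adjusted p = 0.0198 with an estimated correlation. Adjusted over the list alone, 7 cytotoxic genes were higher and 12 naive and memory genes lower, such as Nsg2 (-1.21 ± 0.29), Lef1 (-0.87 ± 0.22) and Slamf6 (-1.12 ± 0.31). B cell genes were lower as a list (median -0.80 over 9 genes, adjusted p = 8.19e-05, adjusted p = 0.0567 with an estimated correlation). Siglech was at 144 ± 58.7 CPM (n = 4) in CXCR6neg against 24.1 ± 53.6 (n = 6) in CXCR6pos.

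Grn did not pass without ND CXCR6pos replicate 1, 2, 3, 4 or 5 or ND CXCR6neg replicate 2, 3 or 5 (adjusted p 0.0686, 0.0729, 0.104, 0.1, 0.0782, 0.146, 0.183 and 0.072). n-R5-8s1 did not pass without ND CXCR6pos replicate 1, 2, 3, 4 or 5, ND CXCR6neg replicate 3 or the library labelled ND CXCR6neg replicate 4 (0.0686, 0.0845, 0.178, 0.1, 0.0782, 0.213 and 0.115). The count was 58 without the library labelled ND CXCR6pos replicate 6, 9 without ND CXCR6neg replicate 5, 1 without ND CXCR6neg replicate 2, and 0 without ND CXCR6pos replicate 1, 2, 3 or 4 or ND CXCR6neg replicate 3. Without the CXCR6pos library lowest and the CXCR6neg library highest in Cxcr6, a choice made after the data were seen and by a measured value, 24 genes were higher and 66 lower. DESeq2 called 0 genes, and 501 genes had an unadjusted p under 0.05 in edgeR and 613 in DESeq2. With the replicate number as a block, in a fit of these 2 groups alone, 33 genes were higher and 42 lower. The fit of these groups without the block called 0.

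Diet was compared next within CXCR6pos liver cells. Pdcd1 (chromosome 1, 94038305 to 94052553, minus strand) was 10.4-fold higher under CD-HFD (3.38 ± 0.25, adjusted p = 8.25e-13, n = 5 and 6). Tox (chromosome 4, 6686353 to 6991557, minus strand) was 5.29-fold higher (2.40 ± 0.23, adjusted p = 9.32e-10) and Havcr2, the inhibitory receptor TIM-3, 12.3-fold higher (3.62 ± 0.46, adjusted p = 2.74e-09). Tcf7 (chromosome 11, 52252371 to 52283014, minus strand) was 4.13-fold lower (-2.05 ± 0.20, adjusted p = 8.97e-15). Il7r was 6.76-fold lower (-2.76 ± 0.24, adjusted p = 5.07e-13) and Ly6c2 4.42-fold lower (-2.14 ± 0.12, adjusted p = 1.7e-30). Cx3cr1 (-1.68 ± 0.29, adjusted p = 5.72e-06) and P2rx7, an ATP-gated channel (-2.94 ± 0.71, adjusted p = 0.00138), fell. In all, 299 genes were higher and 398 lower under CD-HFD.

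The largest increases with CD-HFD in CXCR6pos cells included Coch (41.2-fold, 5.36 ± 0.64), the cytokine gene Il10 (34.8-fold, 5.12 ± 0.66) and the enkephalin precursor Penk (18.9-fold, 4.24 ± 0.52). Adgrg1 (13.3-fold, 3.74 ± 0.39) and Tnfrsf4, the receptor OX40 (12.1-fold, 3.59 ± 0.69), rose as well. Among the largest decreases were Klra9 (18.1-fold, -4.18 ± 0.48), the egress receptor S1pr5 (10.6-fold, -3.40 ± 0.45) and Kcnj8 (9.38-fold, -3.23 ± 0.40). The cytokine gene Tnf (8.97-fold, -3.16 ± 0.40) and Adgrg5 (8.44-fold, -3.08 ± 0.29) fell as well. Nt5e, the ectoenzyme CD73, had 1 count under CD-HFD and 59 under ND, a ratio of 36.8 (95% counting interval 6.35 to 1476).

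Of 20 inhibitory receptor and exhaustion genes, 18 rose with CD-HFD in CXCR6pos and 0 fell, overall and adjusted over the list alone, among them Ctla4 (3.47 ± 0.35), Rgs16 (2.92 ± 0.28), Batf (1.97 ± 0.18) and Entpd1 (1.71 ± 0.22). Of 19 recirculation genes, 14 fell and 0 rose (16 and 1 adjusted over the list alone), with Klf2 at -1.45 ± 0.12 and S1pr1 at -2.00 ± 0.19. Of 16 FOXO1 targets 8 fell and 0 rose (9 and 0 adjusted over the list alone). Of 19 naive and memory genes, 9 fell and 2 rose (14 and 2 adjusted over the list alone), the latter including Cd27 (1.08 ± 0.13). These 4 lists passed camera with both the preset and the estimated correlation. Of the CD4 and regulatory T cell list, 4 of 5 genes rose and 0 fell, overall and adjusted over the list alone (adjusted p = 3.1e-06). They were Ctla4, Tnfrsf4 and Ikzf2 (2.90 ± 0.46), which activated CD8 T cells can also express, and Izumo1r (2.25 ± 0.34). Immediate-early genes gave 11 of 21 lower and 1 higher (12 and 1 adjusted over the list alone, adjusted p = 5.68e-06, adjusted p = 0.217 with an estimated correlation). Fos was at -1.76 ± 0.20 and Jun at -1.70 ± 0.21. Of 10 NK cell genes 7 fell and 2 rose, overall and adjusted over the list alone (adjusted p = 0.0118, adjusted p = 0.147 with an estimated correlation), including Klrk1 (-1.52 ± 0.22) and Klra9. Cytotoxic genes split, with 5 higher, such as Prf1 (0.75 ± 0.14), and 8 lower of 23 (5 and 8 adjusted over the list alone, adjusted p = 0.539). Tissue residency genes split with 8 higher, such as Prdm1 (2.06 ± 0.31), and 4 lower, such as Cd69 (-0.78 ± 0.14), of 19 (10 and 4 adjusted over the list alone, adjusted p = 0.0877). Cd69 did not pass with the library held in 2 columns kept in the liver (adjusted p = 0.0504). Cxcr6 (0.40 ± 0.30), Cd8a (0.04 ± 0.11), Cd8b1 (-0.12 ± 0.10), Il15ra (0.52 ± 0.36) and Foxo1 (-0.66 ± 0.41) did not pass, and Cd3e rose by 0.73 ± 0.10. Gzmb (chromosome 14, 56258838 to 56262260, minus strand, 0.57 ± 0.30) and Fasl (chromosome 1, 161780689 to 161788495, minus strand, 0.25 ± 0.13) did not pass. The ND group held the library labelled ND CXCR6pos replicate 6, which carried 53 of the 57 Siglech counts under ND against 2 under CD-HFD (ratio 17.8, 95% counting interval 4.70 to 150.2). Siglech did not pass (adjusted p = 0.106), and the other 5 ND libraries held at most 2 counts each.

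Within CXCR6neg liver cells, 18 genes were higher and 11 lower under CD-HFD. Pdcd1 was 6.19-fold higher (2.63 ± 0.40, adjusted p = 0.000312, n = 6 and 4) and Rgs16, a regulator of G protein signalling, 3.50-fold higher (1.81 ± 0.33, adjusted p = 0.000312). The transcription factor Batf was 2.65-fold higher (1.41 ± 0.22, adjusted p = 4.56e-05). S1pr5 was 2.99-fold lower (-1.58 ± 0.31, adjusted p = 0.00281). Tox (1.46 ± 0.29), Ikzf2 (2.50 ± 0.51), Penk (3.66 ± 0.63) and Ifi27l2a (1.69 ± 0.32) were also higher and Tnf (-2.23 ± 0.44), Jaml (-1.34 ± 0.24) and Zfp36 (-0.57 ± 0.13) lower. Inhibitory receptor and exhaustion genes gave 5 of 20 higher and 0 lower (10 and 2 adjusted over the list alone, camera passed with both correlations, adjusted p = 0.00501 with an estimated correlation). CD4 and regulatory T cell genes gave 2 of 5 higher and 0 lower (4 and 0 adjusted over the list alone, adjusted p = 5.39e-07, and 0.00501 with an estimated correlation). Immediate-early genes were lower as a list, with 2 of 21 lower and 0 higher (8 and 0 adjusted over the list alone, adjusted p = 8.86e-07, adjusted p = 0.373 with an estimated correlation). Cxcr6 (-1.57 ± 0.43), Cx3cr1 (-0.95 ± 0.27), Cd8a (-0.37 ± 0.11), Cd8b1 (-0.24 ± 0.11), Cd3e (-0.03 ± 0.10), Tcf7 (-0.11 ± 0.15), Foxo1 (-0.36 ± 0.37) and P2rx7 (-1.28 ± 0.65) did not pass. Nor did Fasl (0.09 ± 0.15), Gzmb (-0.07 ± 0.34), Il15ra (-0.45 ± 0.42) or Siglech (0.35 ± 0.47). Without the library labelled ND CXCR6neg replicate 4, 7 genes were higher and 1 lower, and Tox (adjusted p = 0.0706), Ikzf2 and Penk (0.0591 each), Ifi27l2a, Jaml and Zfp36 (0.0744 each) and Tnf (0.0591) lost their calls. The count was 45 without ND CXCR6neg replicate 2 and 19 without replicate 5, where Tox (adjusted p = 0.0519) and Tnf (0.0688) again did not pass. With the library held in 2 columns kept in both groups or in the liver, Tnf (0.137 and 0.15) and Zfp36 (0.746 and 0.749) did not pass, and Ikzf2 did not with voom (0.0538).

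Genes called by both liver diet comparisons numbered 25, with 17 higher and 8 lower in both, against 0.872 and 0.709 expected for independent lists, and 0 in opposite directions. The comparisons share no library, but the labels do not say whether their fractions came from the same animals, and all groups were fitted together. The expected counts are thus a reference and not a test. The shared count was 7 without the library labelled ND CXCR6neg replicate 4, and 16 without ND CXCR6neg replicate 3 or 5. Only Grn was called in both CXCR6 comparisons, lower in both (0.128 expected). This count reached 50 without the library labelled ND CXCR6pos replicate 6, 3 without ND CXCR6neg replicate 5, 2 without the library labelled ND CXCR6neg replicate 4, and 0 without ND CXCR6pos replicate 1, 2, 3 or 4 or ND CXCR6neg replicate 2 or 3.

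Whether the difference between CXCR6pos and CXCR6neg depended on diet was tested as an interaction, in which 27 genes had a positive and 62 a negative term. The fall in CXCR6pos relative to CXCR6neg was larger under CD-HFD for Tcf7 (-1.94 ± 0.26, adjusted p = 1.71e-08) and S1pr1 (-1.98 ± 0.24, adjusted p = 1.22e-09). The same held for Ly6c2 (-1.76 ± 0.16, adjusted p = 3.18e-15) and Il7r (-2.38 ± 0.31, adjusted p = 4.83e-07). Klf2 (-0.99 ± 0.16), the chemokine gene Xcl1 (-2.03 ± 0.45), the cytokine receptor gene Il18r1 (-1.80 ± 0.41) and Nfkbia (-0.77 ± 0.18) also had negative terms. Tdrp (-4.71 ± 0.84), Nt5e (-4.55 ± 0.92) and Pcsk4 (-3.26 ± 0.78) are among the 6 largest. They rest on 1, 1 and 3 counts in CD-HFD CXCR6pos, and such fitted terms are no bound. Positive terms included Bhlhe40 (0.96 ± 0.20), Ccl5 (0.73 ± 0.15), Nkg7 (0.62 ± 0.14), Cd3e (0.76 ± 0.14) and Cd3g (0.65 ± 0.15). Bhlhe40 did not pass with the library held in 2 columns kept in both groups (0.57 ± 0.45, adjusted p = 0.724) or in the liver (adjusted p = 0.735), nor did Nt5e (0.0667) and Pcsk4 (0.0638) with voom. Of 19 recirculation genes 7 had negative and 0 positive terms (11 and 0 adjusted over the list alone), and of 16 FOXO1 targets 7 and 0 (7 and 0 adjusted over the list alone). Of 19 naive and memory genes 5 and 1 did (12 and 2 adjusted over the list alone), and these 3 lists passed at adjusted p = 0.00498 with an estimated correlation. Inhibitory receptor and exhaustion genes had 1 positive and 0 negative terms of 20 (9 and 0 adjusted over the list alone) and a positive list test (adjusted p = 0.00756 with an estimated correlation). Pdcd1 (0.75 ± 0.58), Tox (0.94 ± 0.39), Gzmb (0.64 ± 0.45), Cxcr6 (1.97 ± 0.52, adjusted p = 0.0568) and Cx3cr1 (-0.73 ± 0.41) did not pass. Nor did P2rx7 (-1.66 ± 1.06), Fasl (0.16 ± 0.20), Cd8a (0.41 ± 0.16), Cd8b1 (0.12 ± 0.15), Foxo1 (-0.30 ± 0.56) or Il15ra (0.97 ± 0.55). Without the library labelled ND CXCR6pos replicate 6 and the library labelled ND CXCR6neg replicate 4, 13 terms were positive and 40 negative, and Cd3g did not pass (adjusted p = 0.0795). Without the shallow libraries as well, neither Cd3g (0.147) nor Ccl5 (0.209) passed.

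In the spleen, 2 genes differed between the diets. Lyz2, the lysozyme of myeloid cells, was 2.81-fold higher under CD-HFD (1.49 ± 0.31, adjusted p = 0.0133, n = 6 and 5). Gm26917, an unnamed gene model outside the rule for named genes and chosen after its value was seen, was 2.51-fold lower (-1.33 ± 0.22, adjusted p = 0.00938). Erythroid genes were higher as a list (median 1.17 over 6 genes, 0 passed over all genes and 5 were higher adjusted over the list alone, camera adjusted p = 3.93e-13, and 0.00683 with an estimated correlation). Hba-a1 was at 689 ± 219 CPM (n = 6) against 299 ± 104 (n = 5). Kupffer and macrophage genes, which include Lyz2, were higher as well (1 of 3 genes, 2 adjusted over the list alone, adjusted p = 0.000466, and 0.00683 with an estimated correlation). Inhibitory receptor and exhaustion genes had a median of 0.53 over 20 genes (0 passed over all genes and 3 higher adjusted over the list alone, adjusted p = 1.27e-06, and 0.0465 with an estimated correlation). Pdcd1 was at 1.43 ± 0.37 and Tox at 0.76 ± 0.24. CD-HFD spleen replicates 1 and 2 held 23.3 and 24.8 CPM of Pdcd1, against 34.0 to 75.3 in replicates 3 to 6 and 12.5 to 23.6 under ND. The summed CPM of plasmacytoid dendritic cell markers was 468 and 462 in those libraries, 655 to 729 in replicates 3 to 6 and 463 to 525 under ND. Summed B cell CPM was 6023 ± 763 under CD-HFD (n = 6) and 4609 ± 866 under ND (n = 5), without a call for that list (adjusted p = 0.47). Summed CPM of CD4 and regulatory T cell genes, a list that shares Ctla4 with the exhaustion genes, was 144 ± 55.9 under CD-HFD and 82.1 ± 16.5 under ND. With fry the lists had adjusted p = 0.0931 for erythroid, 0.0582 for macrophage and 0.33 for exhaustion genes. Cxcr6 (0.03 ± 0.32), Cx3cr1 (0.10 ± 0.47), Cd8a (-0.01 ± 0.10), Cd8b1 (-0.04 ± 0.10) and Cd3e (0.05 ± 0.09) did not pass. Nor did Tcf7 (-0.22 ± 0.12), Foxo1 (-0.42 ± 0.25), P2rx7 (-0.36 ± 0.73), Fasl (0.19 ± 0.18), Gzmb (0.64 ± 0.45) or Il15ra (0.38 ± 0.35). The count was 1 without ND spleen replicate 1 or CD-HFD spleen replicate 3 or 5, 4 without CD-HFD spleen replicate 1 and 5 without replicate 2. Lyz2 lost its call without ND spleen replicate 1 (adjusted p = 0.283) or 4 (0.173) and without CD-HFD spleen replicate 2 (0.065), 3 (0.123) or 5 (0.0653), in DESeq2 (0.406), and with the library held in 2 columns kept in the liver (0.057). Gm26917 did not pass with that library kept in both groups (0.117) or in the liver (0.194).

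**Figure D3:**
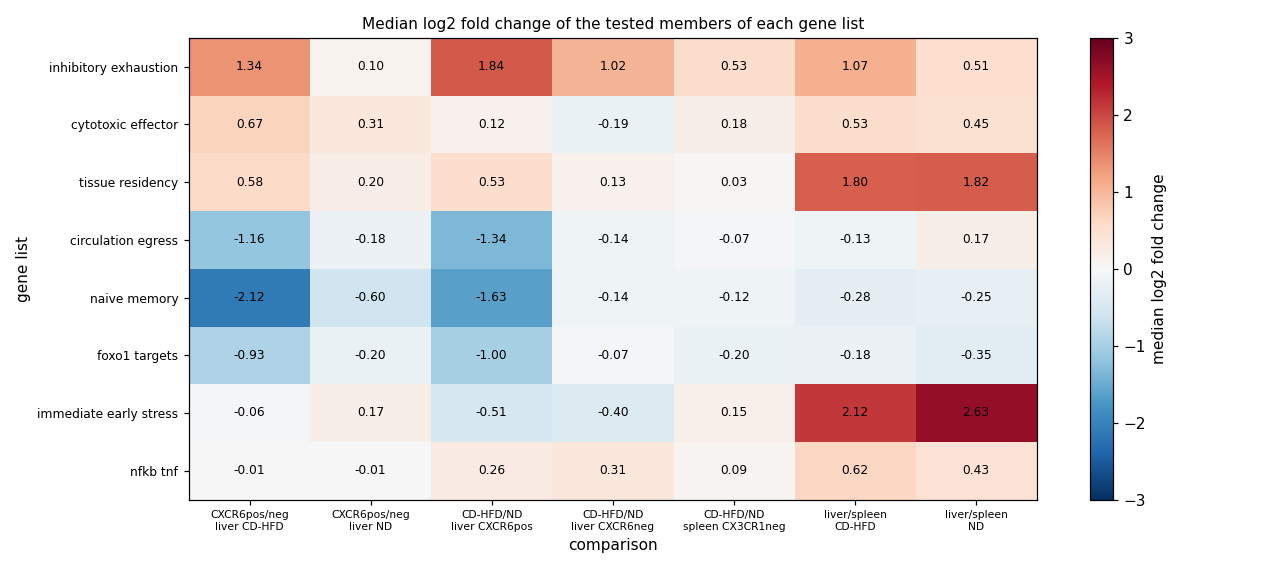
Median log2 fold change over the tested members of 8 gene lists (vertical axis) in 7 comparisons (horizontal axis), with the value in each cell and colour from blue (lower) to red (higher). Naive and memory genes were at -2.12 between CXCR6pos and CXCR6neg under CD-HFD, also with Ccr9 at its bound, and immediate-early genes at 2.12 and 2.63 between liver and spleen.

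Liver CXCR6neg and spleen CX3CR1neg cells were compared under each diet, with the fraction, the tissue and the handling of the tissue changing together. Under CD-HFD the liver cells had 13.2-fold more Junb (3.72 ± 0.11, adjusted p = 4.74e-52, n = 6 and 6), a subunit of the AP-1 transcription factor, and 14.3-fold more Tnfaip3, a brake on NF-kB signalling (3.84 ± 0.15, adjusted p = 1.87e-33). They had 4.03-fold more Cd69, an activation and retention marker (2.01 ± 0.14, adjusted p = 2.1e-24), and 5.38-fold more Gzmb (2.43 ± 0.35, adjusted p = 1.26e-05). Nr4a1 (21.7-fold, 4.44 ± 0.27), Dusp1 (20.5-fold, 4.36 ± 0.23) and Fos (17.8-fold, 4.15 ± 0.23) were among the largest increases. Among the largest decreases were Lyz2 (16.7-fold, -4.06 ± 0.51), Cd81 (11.8-fold, -3.56 ± 0.45) and the immunoglobulin joining chain gene Jchain (11.7-fold, -3.55 ± 0.79). Genes called higher numbered 354 and lower 291. Of 21 immediate-early genes 20 rose and 0 fell (21 and 0 adjusted over the list alone, adjusted p = 5.84e-06 with an estimated correlation). Of 19 tissue residency genes 11 rose and 1 fell (12 and 1 adjusted over the list alone), and of 23 cytotoxic genes 11 rose and 2 fell (12 and 3 adjusted over the list alone), with Ccl4 at 3.15 ± 0.29 and Ifng at 2.83 ± 0.32. Of 20 exhaustion genes 10 rose and 0 fell (14 and 1 adjusted over the list alone), including Pdcd1 (1.48 ± 0.27) and Ctla4 (3.27 ± 0.42). Of 19 NF-kB and TNF genes 11 rose and 1 fell (11 and 3 adjusted over the list alone). These lists held with an estimated correlation, as did B cell genes, of which 6 of 9 were lower and 1 higher (7 and 1 adjusted over the list alone). Beside them Siglech was 10.6-fold higher in the liver (3.41 ± 0.53). Fasl (1.84 ± 0.15) and Tox (0.82 ± 0.21) rose. Cx3cr1 rose (2.49 ± 0.34) and Cxcr6 fell by 1.22 ± 0.39 (adjusted p = 0.0437), the genes by which spleen and liver cells were sorted as negative. Cd8a (-0.19 ± 0.10), Cd8b1 (-0.15 ± 0.10), Cd3e (0.21 ± 0.09), Tcf7 (-0.14 ± 0.12), P2rx7 (1.08 ± 0.72), Foxo1 (-0.32 ± 0.31) and Il15ra (-0.08 ± 0.37) did not pass. Total counts were compared between the groups (exact two-sided permutation p = 0.026, adjusted p = 0.182 over 7 comparisons of depth), and with the log10 total count as a covariate 262 genes were higher and 137 lower, without Tox (0.112) and Cxcr6 (0.133). With the replicate number as a block as well, in a fit of these groups alone, 87 genes were higher and 23 lower. Pdcd1 (adjusted p = 0.706), Ctla4 (0.193), Gzmb (0.548) and Cx3cr1 (0.35) then did not pass. Cxcr6 did not pass with no filter on low counts (0.0872), with shallow libraries left out or with the library held in 2 columns kept in the spleen (0.0527 each), without CD-HFD CXCR6neg replicate 1, 2, 3, 4 or 5 (0.0965, 0.0904, 0.0743, 0.105 and 0.0516) or without CD-HFD spleen replicate 1, 3, 4 or 6 (0.0639, 0.0841, 0.0761 and 0.0572).

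Under ND the liver cells had 41.7-fold more Fos (5.38 ± 0.27, adjusted p = 5.62e-18, n = 4 and 5) and 36.1-fold more Jun (5.17 ± 0.28, adjusted p = 2.68e-15). They had 15.5-fold more Ifng (3.96 ± 0.33, adjusted p = 3.91e-12) and, with the spleen cells sorted for its absence, 11.6-fold more Cx3cr1 (3.54 ± 0.35, adjusted p = 1.39e-13). Hspa1a, a heat-shock protein gene, was 60.0-fold higher (5.91 ± 0.87), and Fosb had 71 counts in the liver group and 2 in the spleen group, a ratio of 69.2 (95% counting interval 18.5 to 583). G0s2 (9.57-fold, -3.26 ± 0.42), Igkc (6.49-fold, -2.70 ± 0.57) and Plbd1 (6.82-fold, -2.77 ± 0.53) were lower. Genes called higher numbered 292 and lower 132. Of 21 immediate-early genes 20 rose and 0 fell, overall and adjusted over the list alone (adjusted p = 5.07e-07 with an estimated correlation). Of 19 tissue residency genes 12 rose and 0 fell, overall and adjusted over the list alone (adjusted p = 3.31e-05 with an estimated correlation). Cytotoxic genes gave 9 of 23 higher and 1 lower (13 and 2 adjusted over the list alone, adjusted p = 0.00139 with an estimated correlation), including Gzmb (3.14 ± 0.42), Gzma (4.09 ± 0.53) and Fasl (1.94 ± 0.18). Erythroid genes gave 3 of 6 higher and 0 lower (5 and 0 adjusted over the list alone, adjusted p = 2.61e-05, adjusted p = 0.0844 with an estimated correlation), with Hba-a1 at 2.21 ± 0.44. Siglech was 11.4-fold higher in the liver (3.51 ± 0.69). B cell genes gave 6 of 9 lower and 1 higher (8 and 1 adjusted over the list alone, adjusted p = 2.95e-07, and 0.00945 with an estimated correlation). Cxcr6 (0.38 ± 0.37), Pdcd1 (0.28 ± 0.56), Tox (0.11 ± 0.33), Cd3e (0.30 ± 0.11), Cd8a (0.18 ± 0.12), Cd8b1 (0.05 ± 0.11), Tcf7 (-0.25 ± 0.14), Foxo1 (-0.39 ± 0.32) and Il15ra (0.76 ± 0.41) did not pass. With the library held in 2 columns kept in both groups 173 genes were higher and 36 lower, and Plbd1 did not pass (0.211). P2rx7 rose by 2.01 ± 0.65 (adjusted p = 0.0415). It did not pass without the library labelled ND CXCR6neg replicate 4 (0.119), ND CXCR6neg replicate 5 (0.381) or ND spleen replicate 1, 2, 3 or 4 (0.0997, 0.151, 0.0728 and 0.105), in DESeq2 (0.14), or with the library held in 2 columns kept in the spleen (0.0557).

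No gene passed the test of whether the diet effect differed between liver CXCR6neg and spleen CX3CR1neg cells: 0 genes were called by edgeR and 0 by DESeq2, with 319 and 409 genes at an unadjusted p under 0.05. The smallest p-values belonged to genes such as Apoe, an apolipoprotein (-2.98 ± 0.58, adjusted p = 0.058), Rab37 (-1.30 ± 0.29, adjusted p = 0.0616) and Batf (1.09 ± 0.29, adjusted p = 0.366). Immediate-early genes had a median of -0.56 over 21 genes (0 passed over all genes and 6 were lower adjusted over the list alone, adjusted p = 3.06e-08, adjusted p = 0.271 with an estimated correlation). Exhaustion genes had a median of 0.43 over 20 genes (1 higher adjusted over the list alone, adjusted p = 0.00145, adjusted p = 0.278 with an estimated correlation). Pdcd1 (1.20 ± 0.62), Tox (0.71 ± 0.39), Cxcr6 (-1.60 ± 0.54), Cx3cr1 (-1.05 ± 0.55) and Tcf7 (0.11 ± 0.19) did not pass. Nor did Gzmb (-0.71 ± 0.57), Fasl (-0.11 ± 0.23), P2rx7 (-0.93 ± 1.03), Foxo1 (0.06 ± 0.46), Il15ra (-0.84 ± 0.55), Cd8a (-0.36 ± 0.15), Cd8b1 (-0.20 ± 0.15) or Cd3e (-0.08 ± 0.14). In simulated data of this design, 81.8% of genes changed 4-fold and 37.3% of those changed 2-fold were recovered. Leaving out ND CXCR6neg replicate 2 gave 5 genes, ND CXCR6neg replicate 3 or CD-HFD spleen replicate 3 gave 2, and CD-HFD CXCR6neg replicate 4 or 6 gave 1.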

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

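The tests of diet dependence, of shallow libraries, of cells of the other fraction in 1 library, and of plasmacytoid dendritic cells and B cells were chosen only after the result was seen. A sample standing apart from its group was sought in 96 tests with Dixon's criterion, and 11 met it. Chance meets it in about 1 of 20 where values are normally distributed, which groups of zeros and few counts are not. In ND CXCR6pos replicate 1, the shallowest library, 4329 genes were detected against 10703 to 13197 in the rest of the group, and Cd8a was at 739 CPM against 1366 to 1677. Siglech was at 133 CPM in the library labelled ND CXCR6pos replicate 6 against 0 to 6.68, and at 12.4 in CD-HFD CXCR6pos replicate 3 against 0 in the rest. Tox was at 573 CPM in CD-HFD CXCR6pos replicate 1 against 371 to 411, Cd8a at 1050 in CD-HFD CXCR6neg replicate 1 against 836 to 863, and P2rx7 at 36.2 in CD-HFD CXCR6neg replicate 5 against 0 to 8.87. In ND spleen replicate 5, Cx3cr1 was at 31.3 CPM against 2.62 to 10.2, P2rx7 at 25.1 against 1.71 to 4.60, and Tcf7 at 257 against 357 to 381. Cx3cr1 was at 28.2 CPM in CD-HFD spleen replicate 4 against 5.38 to 9.71. Some of these values rest on few counts: Siglech in CD-HFD CXCR6pos replicate 3 on 2 and P2rx7 in CD-HFD CXCR6neg replicate 5 on 3. Cx3cr1 rests on 5 counts in ND spleen replicate 5 and 9 in CD-HFD spleen replicate 4.

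The difference between CXCR6pos and CXCR6neg differed between the diets by the interaction test for 89 genes. The terms were -1.94 for Tcf7, -1.98 for S1pr1, -1.76 for Ly6c2, -2.38 for Il7r, -0.99 for Klf2, -2.03 for Xcl1, -1.80 for Il18r1, -0.77 for Nfkbia, -4.71 for Tdrp, -4.55 for Nt5e and -3.26 for Pcsk4. They were 0.96 for Bhlhe40, 0.73 for Ccl5, 0.62 for Nkg7, 0.76 for Cd3e and 0.65 for Cd3g. The library held in a liver and a spleen column, used in no comparison, held 326 CPM of Cxcr6 without TMM scaling.

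Other splits of the same samples, 100 for each comparison with the real one included, were fitted alike. No other split gave as many genes as the real one for CXCR6pos against CXCR6neg under CD-HFD (688 genes, highest of the other splits 389, 1 of 100 as large). The same held for diet in CXCR6pos (697, highest other 693, 1 of 100) and in CXCR6neg (29, highest other 11, 1 of 100). It held as well for liver against spleen under CD-HFD (645, highest other 193, 1 of 100) and under ND (424, highest other 349, 1 of 100). Such counts were thus uncommon among splits, at a share under 0.05 not adjusted over the 9 comparisons. Chance is not excluded by them, since only part of the possible splits was fitted and 1 of 100 is the smallest share possible. For the interaction of diet and CXCR6 (89, highest other 112, 2 of 100) another split gave more genes than the real one. The count was thus uncommon among splits rather than beyond them. Splits for the interactions shuffled diet within each fraction, which also removes the diet effect common to both fractions. They therefore cannot test an interaction alone. For diet in CXCR6pos the real count lay little above the highest other. Counts as large were more frequent for CXCR6pos against CXCR6neg under ND (2, highest other 86, 29 of 100) and diet in the spleen (2, highest other 26, 7 of 100). Chance could not be excluded there either. For the interaction of diet and tissue (0, highest other 2, 100 of 100) the splits could decide nothing, since every split gives at least 0 genes. The splits with 86 and 26 genes, many times the real counts, point to a structure among those samples, which was not tested.

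Few genes passed between CXCR6pos and CXCR6neg under ND, 2 against 688 under CD-HFD. With the replicate number as a block, 75 genes passed under ND, against 0 from only these groups without it. Leaving out the shallow libraries gave 0 genes. That cannot decide whether they hide a difference, because leaving out a library also leaves fewer to detect one. Without ND CXCR6pos replicate 2, 3 or 4, which are not shallow, the count was 0 as well. A mutual swap of labels between the CXCR6pos library lowest and the CXCR6neg library highest in Cxcr6 cannot be told apart from other causes. Only 1 of the 2, the library labelled ND CXCR6pos replicate 6 (-0.80), scored nearer to the other fraction on the genes that separate the fractions under CD-HFD. The genes lower in CXCR6pos, plasmacytoid dendritic cell genes among them, are part of that score, so it is not separate from the markers given next. On the higher genes alone that library was at 6.77. ND CXCR6pos replicate 5 was at 6.78 and the library labelled ND CXCR6neg replicate 4 at 6.75, so these genes cannot place it in either fraction. The library labelled ND CXCR6neg replicate 4 (-0.78) scored nearer to its own fraction and held 854 CPM of plasmacytoid dendritic cell markers and 64.3 CPM of Siglech, which speak against a swap, while its 450 CPM of Cxcr6 speak for one. That the library labelled ND CXCR6pos replicate 6 holds cells of the other fraction is a hypothesis in line with its 1670 CPM of these markers, against 192 to 287 in the other ND CXCR6pos libraries and 854 to 1811 in ND CXCR6neg. A smaller difference under ND stays open beside it, with 89 genes in the interaction and 53 without these libraries.

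Plasmacytoid dendritic cell genes were lower in CXCR6pos than in CXCR6neg under CD-HFD. A single library as the source is argued against by Siglech, whose highest adjusted p without 1 library was 0.0015. B cells in CXCR6neg stay open, since Igkc was at 0.64 ± 0.57 toward CXCR6pos whereas 5 of 9 B cell genes fell (adjusted p = 4.14e-08), among them Ighm (-1.77 ± 0.40), with summed B cell CPM of 651 ± 170 in CXCR6pos and 1990 ± 107 in CXCR6neg. Plasmacytoid dendritic cells among CXCR6neg cells may be a source, since 6 of 8 other tested markers were lower, including Irf8, Tcf4, Pld4 and Ly6d, the last of which is also among the B cell genes that fell. That marker list was written after the data were seen, so these falls are not an independent test. Whether the sort removed both kinds of cell was not tested, nor was a biological explanation within the CD8 T cells.

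One library stood in a liver and a spleen column. Its score on the genes that separate liver from spleen under CD-HFD was -1.82, against -2.15 to -1.79 in ND spleen and -0.62 to -0.36 in ND CXCR6neg, which is in line with a spleen library copied into a liver column and argues against the converse. Its 502 CPM of plasmacytoid dendritic cell markers lay within the 463 to 525 of ND spleen and below the 854 to 1811 of ND CXCR6neg. Its 24.6 CPM of Cx3cr1, without TMM scaling, lay below the 42.2 to 151 of ND CXCR6neg. That value lay within the range of ND spleen only through replicate 5 (29.6 CPM, on 5 counts). The other ND spleen libraries held 2.34 to 9.80 CPM. Its 326 CPM of Cxcr6, without TMM scaling, go the other way, above the 157 to 242 CPM of ND spleen and within the 36.2 to 434 of ND CXCR6neg. So does its score on the genes that separate the fractions under CD-HFD (-1.08). That score lay above the -1.32 to -1.15 of ND spleen and within the -1.24 to -0.78 of ND CXCR6neg. No biological explanation was tested.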

How the results depend on the processing

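The fits with the library held in 2 columns, without the library labelled ND CXCR6pos replicate 6 and the library labelled ND CXCR6neg replicate 4 (the pair lowest and highest in Cxcr6 of their groups), and the count shared by both diet comparisons were chosen after the data were seen. Of the gene and list tests checked, none passed in opposite directions under different settings, but many changed in other ways. With fry, 202 of 261 list tests were the same, 29 weaker, 9 stronger and 21 changed otherwise. Without each library in turn, 2976 of 3094 gene results were the same, 44 weaker, 25 stronger and 49 changed otherwise. For CXCR6pos against CXCR6neg under ND, the 2 genes became 0 with DESeq2, RLE, only the groups compared or shallow libraries left out. They became 18 with no filter on low counts and 14 with voom. They became 14 with the repeated library in both groups or in the liver, 1 with it in the spleen, 90 without that pair and 83 also without shallow ones. The 1 gene shared with CD-HFD became 0 with DESeq2, RLE, only the groups compared or shallow libraries left out, 9 with no filter and 14 with voom. It became 9 and 10 with the repeated library in both groups or in the liver, and 73 and 70 without that pair, alone and with shallow ones. Diet in CXCR6neg gave 47 genes with only the groups compared, 55 and 53 with the repeated library in both groups or in the liver, and 9 and 8 without that pair. The 25 genes shared by both liver diet comparisons became 38 with the repeated library in both groups and 7 and 6 without that pair. Diet in the spleen gave 8 genes with no filter, 4 with only the groups compared, 5 with voom, and 1 and 0 with the repeated library in both groups or in the liver, where Gm26917 lost its call. The interaction of diet and CXCR6 gave 53 and 54 genes without that pair. Liver against spleen gave 399 genes under CD-HFD with the total count as a covariate and, under ND, 209 and 245 with the repeated library in both groups or in the liver. The interaction of diet and tissue, at 0, gave 1 with RLE, 4 with no filter, 8 with only the groups compared, 2 with voom and 2 with the repeated library in the spleen. The cause was not tested.

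The labels do not say whether equal replicate numbers mark paired samples. Correlations between same numbers reached at most 0.084 in any comparison, which is weak but cannot rule out pairing. Between the fractions under ND they were 0.084, 0.022, 0.026 and 0.051 for replicates 2 to 5, against medians of -0.045, 0.014, -0.0004 and -0.060 for other numbers. Between liver and spleen under CD-HFD, all but replicate 3 lay below those medians. Fits with the number as a block held only the groups compared, so the count from only those groups without a block is set beside each. For diet within a fraction, the block joined equal numbers across the diets. There it is no test of samples paired by animal. With the block, counts were 75 against 0 for the fractions under ND, where only numbers 2 to 5 are paired, 56 against 0 for the genes shared with CD-HFD, and 418 against 538 for diet in CXCR6pos. They were 12 against 4 for diet in the spleen and 6 against 8 for the interaction of diet and tissue. With block and total count together they were 76 against 0, 56 against 0 for the shared genes and 7 against 8 for that interaction. For liver against spleen they were 110 against 661 under CD-HFD and 227 against 362 under ND. Under CD-HFD, Pdcd1 (0.54 ± 0.40, adjusted p = 0.706), Ctla4 (1.59 ± 0.57, 0.193), Gzmb (1.63 ± 0.66, 0.548) and Cx3cr1 (1.58 ± 0.69, 0.35) then did not pass, although they passed with the total count alone. In the interaction of diet and CXCR6, Nkg7 (adjusted p = 0.0557), Il18r1 (0.0648) and Cd3g (0.126) did not pass with both, nor Cd3g (0.0735) with the block alone. Zfp36 did not pass with the block for diet in CXCR6neg (0.0782). Of pairs, those correlating best with their own number were 2 of 5, 1 of 4, 3 of 5, 2 of 4, 2 of 5, 1 of 6 and 1 of 4.

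Leaving out 1 library in turn gave 561 to 660 genes for the fractions under CD-HFD and 0 to 58 under ND, 559 to 729 for diet in CXCR6pos, 8 to 45 in CXCR6neg and 1 to 5 in the spleen. It gave 67 to 109 for the interaction with CXCR6, 495 to 646 and 321 to 432 for liver against spleen under CD-HFD and ND, and 0 to 5 for the interaction with tissue. Shared genes were 0 to 50 for the fractions and 7 to 33 for diet. Of 261 list tests, 211 kept their side of the threshold with an estimated correlation and 50 lost their call. In simulated data, 17.9% of 1.5-fold changes were recovered between the fractions under CD-HFD, and what depth alone limits was not separated from the number of libraries and their spread.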
